A study of Homo sapiens with 8 samples.

How the data were processed

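Gene expression was measured by sequencing polyA RNA from HepG2, an established human hepatocellular carcinoma line, on a Genome Analyzer II. Cells were grown with 10% serum, moved to 1% serum 24 h after plating, left for 8 h and then treated for 18 h, per the labels' protocols. The groups were vehicle (DMSO, 3 libraries), genistein (3 libraries) and BMP6 at 50 ng/ml (2 libraries), and every well held 1% DMSO. The series design gives the genistein dose as 10 micromolar, whereas the treatment protocol prints the same figure in millimolar, and this conflict was left open. The series design calls the libraries biological replicates. RNA integrity numbers were above 8.5, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

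The deposited files hold 1 FPKM value (fragments scaled to transcript length and library size) per Ensembl gene and library, with an interval around it and a status, per the file headers. TopHat 1.1.0, Bowtie, Cufflinks 1.0.3, Cuffdiff and the genome build hg18 are named in the submitters' processing notes, which give no settings or order. The authors' scaling of the FPKM values is not given in the sources used here. FPKM totals ranged from 1704599 to 3105197 per library. The low values were checked for steps of whole reads: among the 1000 lowest values above 0 in each library, the Spearman correlation with transcript length lay between -0.0811 and 0.0775, so no read counts were recovered and no count model was used. The deposited interval had a half-width equal to the square root of FPKM multiplied by 2, within a tolerance of 0.05, for 78.59% to 84.41% of genes, and therefore gave no information on depth. The sequencing depth of each library is unknown, and neither counting intervals nor detection floors were computed.

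The files list 20897 genes on 24 chromosomes, and 7494 of them were at 0 FPKM in all 8 libraries. Each library had between 8347 and 10364 genes at exactly 0 and between 31 and 55 genes with a FAIL status. An exact 0 can be a failed estimate, since some genes were at 0 in 1 library and high in the others, although none of 12 housekeeping genes was at 0. A gene is therefore described as listed at 0, with the value of each library. Symbols were matched to 19069 of the gene IDs through a table of gene names. Symbols in the gene lists were also looked up through GENCODE v29 names and RefSeq synonyms. Coordinates are those of the files, in hg18, with starts converted to count from 1, because 258 of 269 olfactory receptor spans were then multiples of 3. No hg18 annotation was used, so exons and untranslated regions are not described. Transcript GC content and length came from GENCODE v29 transcripts and were available for 11993 of the tested genes (94.7%).

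Genes with at least 1 FPKM in at least 2 libraries were tested (12661 genes, 11980 of them with a symbol). Values were converted to log2(FPKM + 1) with no further scaling. All 8 libraries entered a single limma fit (version 3.58.1, R 4.3.3) with an intensity trend in the variance, so that the 3 groups shared an estimate of the spread (5 residual and 3.22 prior degrees of freedom). The 3 contrasts were genistein against DMSO, BMP6 against DMSO and genistein against BMP6, each two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of low genes, and the SE is that of limma. For HAMP an exact two-sided permutation test was added (SciPy 1.17.1, Python 3.11.15).

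A set of 30 gene lists and 4 lists of markers of other cell types was written from general knowledge before the data were examined. Lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 30 lists within a comparison. Beside each count over all tested genes, the count adjusted over the list alone is given. Camera with an estimated correlation and fry were run as alternatives, and no list was called in any comparison with an estimated correlation. "With an estimated correlation" always introduces the adjusted p of that test.

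Genes were named by a rule fixed at the same time. It takes HAMP and up to 10 BMP target genes with the smallest p after BMP6, the 10 largest rises and 10 largest falls against DMSO after each treatment (5 and 5 for genistein against BMP6) among genes past the threshold whose libraries did not overlap, and up to 4 members of each list that was called or had at least 2 members past the threshold. Not every gene that the rule covers is named in the text. Small noncoding RNAs, unnamed loci and IDs without a symbol were left out of the largest changes: 39 of 773 rises and 66 of 754 falls after genistein, 5 of 43 and 11 of 63 after BMP6, and 9 of 81 and 6 of 95 between the treatments. Genes named beyond that rule (ALB, APOA2, ATF4, PSPH, MKI67, PDGFRB, LYZ, CD68, CDH1, SOX9 and CYP1A1) were chosen after their values were seen.

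The fit was tested on simulated data in which 200 of the 12661 genes were changed. For genistein against DMSO it recovered 24% of genes changed by 2 on the log2 scale, 58% at 3 and 84% at 4, with 4 false calls among 87, and none of those changed by 1. For BMP6 against DMSO it recovered 18%, 52% and 86%, with 1 false call among 79, and again none at 1. Noise was drawn independently for each gene, and far fewer genes were changed than the 1527 that passed after genistein. These rates therefore do not carry over directly to the fits of the data. The covariance and correlation of the log2 changes against DMSO were set beside 100 simulated data sets in which no gene changed. In each set all 8 libraries were drawn anew with noise independent for each gene, and both comparisons shared the drawn DMSO values. Alternatives fixed at the same time were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, fits of 2 groups only, a block for the replicate number, no variance trend, robust fitting, library weights, and leaving out each library in turn. After seeing the data, 4 more were added: genes above 0 in all libraries, genes without a FAIL status, removal of each library's trend with transcript GC, and leaving out DMSO 1, genistein 2 and BMP6 1 together. Figures were drawn with Matplotlib 3.10.9.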

Results

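Transcript levels were measured in 8 libraries of HepG2 cells, a human liver carcinoma line used as a model of hepatocytes. The cells received vehicle (DMSO, n = 3), genistein (n = 3), a soy isoflavone known as a tyrosine kinase inhibitor and oestrogen receptor ligand, or BMP6 (n = 2), the bone morphogenetic protein that signals iron loading to hepatocytes. The values are FPKM as the authors computed them, and the depth of the libraries is unknown. APOA2, an apolipoprotein of high density lipoprotein, was the most abundant transcript in the 6 DMSO and genistein libraries, and ALB, the gene of serum albumin, in both BMP6 libraries. Correlations across tested genes ranged from 0.884 to 0.963 within DMSO and from 0.913 to 0.96 within genistein, and the BMP6 pair had 0.847. Both BMP6 libraries correlated more with a library of another group, BMP6 1 with genistein 3 (0.889) and BMP6 2 with DMSO 3 (0.912). The first principal component (35.8% of variance) placed the DMSO libraries apart from the genistein libraries, and BMP6 1 stood apart on the second (21.7%). The third (19.5%) set DMSO 1 and genistein 2 apart from the other libraries, with scores of -76.3 and -78.8. DMSO 1 and genistein 2 also had the most tested genes at 0 (1679 and 2167, against 356 to 962 in the others).

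**Figure D1:**
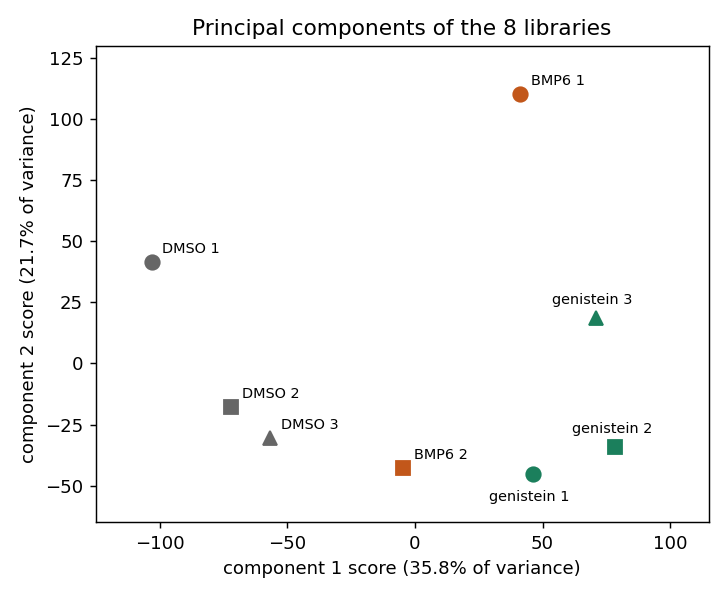
Scores of the 8 libraries on the first 2 principal components of log2(FPKM + 1) over 12661 tested genes, with colours for the 3 groups and marker shapes for the replicate number. DMSO libraries score between -103.1 and -56.85 on component 1 and genistein libraries between 46.07 and 78.49, while BMP6 1 has the highest score on component 2 (110.5).

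The title of the series names hepcidin, the liver hormone that limits iron export into plasma, which HAMP encodes. HAMP (ENSG00000105697; hg18, chromosome 19, 40465250 to 40467886) was listed at 0 FPKM in all 3 DMSO libraries. It stood at 22.2, 34.4 and 22.8 FPKM in genistein 1, 2 and 3, and at 2563 and 6425 FPKM in BMP6 1 and 2. HAMP rose by 4.75 ± 0.42 (log2, SE) after genistein (limma adjusted p = 0.00169) and by 11.99 ± 0.46 after BMP6 (limma adjusted p = 4.6e-05). It was lower after genistein than after BMP6, with a log2 difference of -7.24 ± 0.46 (limma adjusted p = 0.00086) that corresponded to 151-fold on the FPKM + 1 scale. The exact two-sided permutation test gave p = 0.1 for genistein against DMSO (3 against 3) and p = 0.2 for BMP6 against DMSO and for genistein against BMP6 (3 against 2), which are the smallest values those designs allow.

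**Figure D2:**
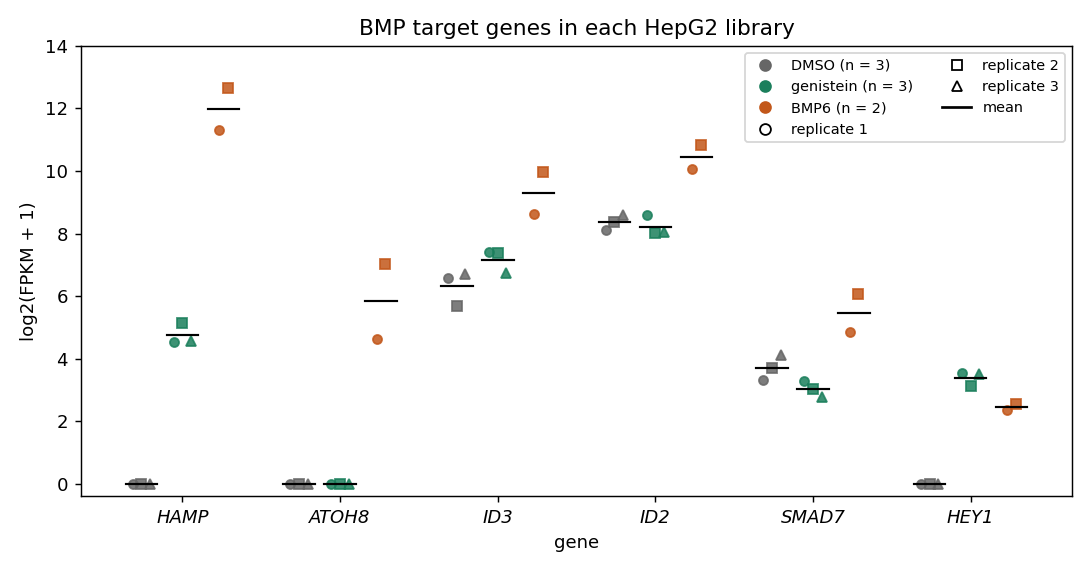
Expression of 6 BMP target genes in each library as log2(FPKM + 1), with colours for DMSO (n = 3), genistein (n = 3) and BMP6 (n = 2), marker shapes for the replicate number and black bars for group means. HAMP was listed at 0 in DMSO, intermediate after genistein and highest after BMP6, and ATOH8 was above 0 after BMP6 alone.

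Among 25 tested genes of iron handling, TMPRSS6, which encodes the protease matriptase-2 that restrains hepcidin expression, fell after genistein from 21.7 ± 2.29 to 3.42 ± 0.649 FPKM (SD, n = 3 each; log2 change -2.37 ± 0.35, limma adjusted p = 0.00823). BMP4, another BMP ligand, fell by 2.54 ± 0.52 on the log2 scale (limma adjusted p = 0.0217), and ALAS1, the first enzyme of heme synthesis, rose by 1.25 ± 0.31 (limma adjusted p = 0.0372). The remaining 22 did not pass the threshold, the counts were the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.564). Of 17 tested BMP and SMAD target genes, 3 rose after genistein (4 higher and 1 lower adjusted over the list alone): HAMP, HEY1 and FST. HEY1, a Notch and BMP responsive repressor, was listed at 0 in DMSO and stood at 10.7, 7.81 and 10.3 FPKM after genistein, and FST, which encodes the activin antagonist follistatin, rose by 2.00 ± 0.48. The inhibitors of differentiation ID3 (log2 change 0.85 ± 0.45) and ID2 (-0.14 ± 0.34) and the inhibitory SMAD7 (-0.68 ± 0.44) did not pass, ATOH8 was listed at 0 in all DMSO and genistein libraries, and the list was not called (camera adjusted p = 0.177). The 2 iron handling genes that fell were 1 without DMSO 1, 2 or 3 or without genistein 1, 2 or 3, and no fit without 1 library moved the 3 BMP targets below 2.

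Of 12661 genes tested, 773 were higher and 754 lower after genistein than in DMSO, 1527 in all. Of these 1527 genes, 185 had either the genistein or the DMSO group listed at 0 in every library. CSTA, which encodes the protease inhibitor cystatin A, was listed at 0 in every DMSO and BMP6 library and stood at 173, 134 and 98.7 FPKM in genistein 1, 2 and 3 (limma adjusted p = 0.000875). OSCAR, an immunoglobulin-like receptor, PAEP, the gene of glycodelin, and IGFBP3, an insulin-like growth factor binding protein, were likewise listed at 0 without genistein, and at 29.9 to 73.9, 38.1 to 71.2 and 34 to 64.2 FPKM with it. METRNL, the gene of a secreted protein, was listed at 0 in DMSO and at 59.7 to 147 FPKM after genistein. GDF15, a stress-induced cytokine, rose from 662 ± 214 to 31792 ± 16661 FPKM (SD, n = 3 each; log2 change 5.48 ± 0.91, limma adjusted p = 0.0114). The other large rises were MT1X, a metallothionein whose reads may be shared with its paralogs, PHLDA2, S100A14 and UPP1, with log2 changes from 5.37 to 6.35.

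The largest falls after genistein included DIO1, the deiodinase that activates thyroid hormone (112 ± 72.5 to 1.65 ± 2.85 FPKM, log2 change -5.77 ± 0.76, limma adjusted p = 0.00611), and CIDEB, a protein of lipid droplets and lipoprotein assembly (369 ± 187 to 9.28 ± 5.41 FPKM, log2 change -5.19 ± 1.01, limma adjusted p = 0.0179). The linker histone gene H1-4, SMPX and ASB9 were listed at 0 in all genistein libraries and at 41.4 to 57.5, 38.6 to 44.2 and 35.5 to 37.6 FPKM in DMSO. TUBB1, SAMD11 and OPN3, an opsin gene, had log2 changes of -5.44, -5.41 and -5.28. NPIPA1 (log2 change -7.01), a member of a near-identical duplicated family, and the pseudogene HSP90AA6P, listed at 0 after genistein, are uncertain because reads could be split among copies. Of these 20 largest changes, 13 passed the threshold in each fit without 1 library. GDF15 and SAMD11 lost it without DMSO 2, CIDEB without DMSO 1, DMSO 2, genistein 2 or genistein 3, MT1X, PHLDA2 and UPP1 without DMSO 1, DMSO 2 or any genistein library, and HSP90AA6P without any DMSO or genistein library, at adjusted p of at most 0.1. Of all 97 genes that the naming rule covers and that passed after genistein, 43 passed in each such fit and 54 lost the threshold in 1 or more, 53 of them without DMSO 2 and 49 without genistein 3, at adjusted p of at most 0.175.

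All 1527 genes had genistein libraries that did not overlap the DMSO libraries, as did 43.9% of all genes tested, against 10% by chance. The count was 229 without DMSO 2, 685 without DMSO 3, 595, 577 and 280 without genistein 1, 2 and 3, and 2660 and 2671 without BMP6 1 and BMP6 2. The balance of 773 higher and 754 lower was not stable: it was 194 and 401 without genistein 1, and 927 and 1311 with median-of-ratios scaling. Median-of-ratios scaling moved the median log2 change of all genes by -0.102 for genistein against DMSO and by -0.154 for genistein against BMP6, and the changes named here are larger than these shifts.

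Genes of the amino acid response driven by ATF4 rose after genistein in 15 of 23 tested, with 1 lower (17 higher and 1 lower adjusted over the list alone). SLC7A11, the cystine transporter, rose from 5.09 ± 1.05 to 117 ± 8.65 FPKM (SD, n = 3 each; log2 change 4.28 ± 0.31, limma adjusted p = 0.00151). ASNS, asparagine synthetase, went from 108 ± 23.7 to 1581 ± 299 FPKM, MTHFD2, a mitochondrial folate enzyme, from 91.5 ± 25.5 to 1065 ± 211, and DDIT3, which encodes the stress factor CHOP, from 80.9 ± 18.9 to 819 ± 185. PSPH, the phosphatase of serine synthesis, was the member that fell (log2 change -1.49 ± 0.34), and the ATF4 transcript itself did not pass (0.51). The list was called higher (camera adjusted p = 1.19e-09; adjusted p = 0.415 with an estimated correlation). Its count of rises was 7 without DMSO 2 and 9 without genistein 1, 2 or 3.

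NRF2 target genes, which serve glutathione synthesis and detoxification, rose in 9 of 20 tested with none lower (10 adjusted over the list alone). Besides SLC7A11 they included GCLC, the catalytic subunit of glutathione synthesis (70.7 ± 5.06 to 318 ± 82.2 FPKM), and the near-identical aldo-keto reductases AKR1C1 and AKR1C2 (log2 changes 3.68 ± 0.58 and 2.85 ± 0.43), whose reads could be split between them. The list was called higher (camera adjusted p = 6.9e-06; adjusted p = 0.415 with an estimated correlation). Of 23 immediate early and ERK response genes, 6 rose and none fell (6 adjusted over the list alone), among them SPRY4, a feedback inhibitor of receptor signalling (33.1 ± 3.35 to 257 ± 32 FPKM), DUSP5, an ERK phosphatase (5.4 ± 2.78 to 121 ± 47.2 FPKM), and the receptor EPHA2 (44.9 ± 10.4 to 240.3 ± 16.2 FPKM). DUSP4, a related phosphatase, was listed at 0 in DMSO and stood at 3.69 to 8.76 FPKM after genistein. The immediate early list was called higher (camera adjusted p = 0.000665; adjusted p = 0.415 with an estimated correlation). The NRF2 count was 3 without DMSO 2 and 5 without genistein 1 or genistein 3, and the immediate early count was 3 without DMSO 2 or genistein 3.

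Genes of G2 and mitosis were higher after genistein in 19 of 33 tested, with none lower (24 adjusted over the list alone), and 32 of the 33 had a positive change. The spindle checkpoint kinase TTK rose from 18.4 ± 3.42 to 110.0 ± 31.3 FPKM (SD, n = 3 each; log2 change 2.50 ± 0.38, limma adjusted p = 0.00924) and the mitotic kinase AURKA from 126 ± 41 to 452 ± 7.55 FPKM. CENPE, a kinetochore motor, PRC1, a midzone protein, CCNB1, cyclin B1, and the proliferation marker MKI67 had log2 changes of 2.24, 2.20, 1.59 and 1.23. The list was called higher (camera adjusted p = 2.15e-10; adjusted p = 0.415 with an estimated correlation). The count was 10 without DMSO 1, 0 without DMSO 2, 7 without DMSO 3, 5 without genistein 1, 4 without genistein 2 and 0 without genistein 3. Replication-dependent histone genes went the other way: H1-4 and H2BC21 fell among 13 tested (3 adjusted over the list alone), 11 of the 13 had a negative change, and the list was called lower (camera adjusted p = 0.00417; adjusted p = 0.602 with an estimated correlation). Because polyA RNA was sequenced, these values cover only histone transcripts with a polyA tail and do not measure total histone RNA. The histone count was 1 without DMSO 1, 2 or 3 or genistein 1, 2 or 3, and 5 without BMP6 1 or BMP6 2.

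Cholesterol synthesis genes fell after genistein in 9 of 24 tested, and 1 rose (15 lower and 1 higher adjusted over the list alone). SQLE, the squalene epoxidase, fell from 437 ± 261 to 37.7 ± 2.62 FPKM (SD, n = 3 each; log2 change -3.35 ± 0.41, limma adjusted p = 0.00494). LSS, the lanosterol synthase, fell from 111 ± 26.3 to 19.8 ± 3.93 FPKM (log2 change -2.43 ± 0.31, limma adjusted p = 0.00611). The list was called lower (camera adjusted p = 1.5e-07; adjusted p = 0.415 with an estimated correlation). Fatty acid and triglyceride synthesis genes fell in 4 of 16 tested (5 adjusted over the list alone): PNPLA3, SCD, ACLY and FADS2. SCD, the stearoyl desaturase, went from 610 ± 218 to 158 ± 24.3 FPKM, and the list was called lower (camera adjusted p = 0.0213; adjusted p = 0.538 with an estimated correlation). PPAR-alpha and fatty acid oxidation genes fell in 4 of 16 tested (6 lower and 1 higher adjusted over the list alone), including FABP1, CREB3L3 and SLC25A20. FABP1, the liver fatty acid binding protein, went from 10744 ± 1921 to 423 ± 107 FPKM, and the list was called lower (camera adjusted p = 0.02; adjusted p = 0.415 with an estimated correlation). The cholesterol count was 4 without DMSO 2, 5 without genistein 2 or 3 and 14 without BMP6 1 or BMP6 2. The fatty acid synthesis count was 2 without DMSO 1 and 1 without DMSO 2, DMSO 3 or any genistein library, and the PPAR-alpha count was 2 without DMSO 2 or genistein 3. The fatty acid synthesis call was lost with arrayWeights (camera adjusted p = 0.0612) and with DMSO 1, genistein 2 and BMP6 1 left out (0.101), and the PPAR-alpha call among genes above 0 in all libraries (0.116).

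CYP7A1, the first enzyme of bile acid synthesis, and CYP8B1, which sets the cholic acid share, were listed at 0 in all genistein libraries and at 21.6 to 27.1 and 16.9 to 24.7 FPKM in DMSO. They were among 6 of 14 xenobiotic enzymes and transporters that fell, while 2 rose, including the efflux pump ABCB1 (log2 change 1.95 ± 0.27). The xenobiotic list was not called (4 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.155). Of 11 NF-kappa B and chemokine genes 4 fell (4 adjusted over the list alone): CXCL8, listed at 0 after genistein, TNFAIP3, NFKBIA and NFKBIZ. CXCL8 is a chemokine gene, the others encode inhibitors or regulators of NF-kappa B, and the list was called lower (camera adjusted p = 0.00768; adjusted p = 0.523 with an estimated correlation). Of 15 interferon response genes 3 fell (3 adjusted over the list alone), IFIT1, IFIT3 and IFI6 (camera adjusted p = 0.0482; adjusted p = 0.523 with an estimated correlation). Coagulation and complement genes had 4 of 23 lower and 1 higher (the same adjusted over the list alone), with CFI, C8A and PROZ lower and SERPINC1, the gene of antithrombin, higher (camera adjusted p = 0.0299; adjusted p = 0.66 with an estimated correlation). The interferon call was lost without DMSO 2, DMSO 3, genistein 1 or genistein 2 (camera adjusted p = 0.0754, 0.0688, 0.0737 and 0.0564). It was also lost with no filter (0.0653), a mean of at least 5 FPKM (0.0807), median-of-ratios scaling (0.0507), quantile normalization (0.075) and genes above 0 in all libraries (0.203). The coagulation call was lost without DMSO 2 or DMSO 3 (camera adjusted p = 0.0689 and 0.0688).

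Falls in the xenobiotic, NF-kappa B, interferon and coagulation lists numbered 2, 1, 1 and 0 without DMSO 2. They numbered 3, 2, 2 and 4 without DMSO 1, and 2, 2, 2 and 0 without DMSO 3. They numbered 2, 3, 2 and 1 without genistein 1, 2, 2, 2 and 1 without genistein 2, and 2, 2, 1 and 0 without genistein 3. The 2 xenobiotic rises were 1 without any DMSO or genistein library and 4 without BMP6 1 or BMP6 2. Of 30 lists, camera called 4 higher and 7 lower after genistein, fry called 13, and camera with an estimated correlation called 0.

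**Figure D3:**
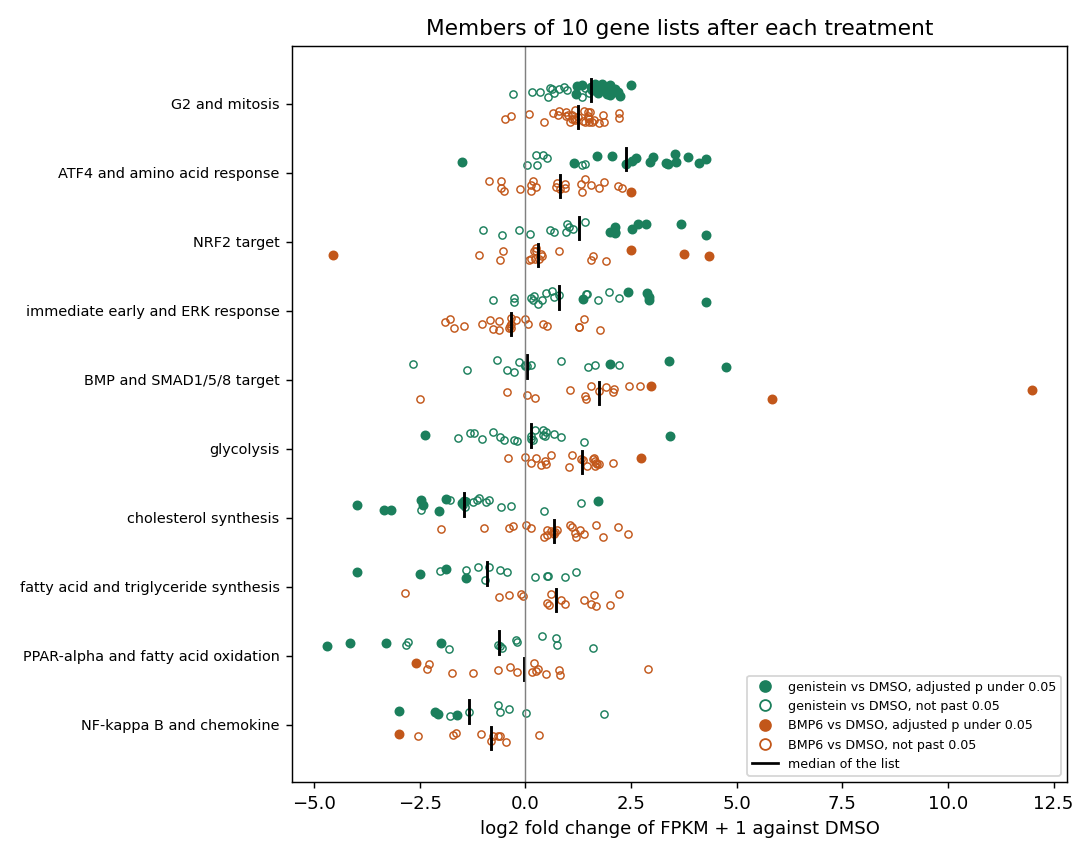
Log2 fold change of each tested member of 10 gene lists against DMSO, for genistein (green) and BMP6 (orange), with filled points for adjusted p under 0.05, open points for the rest and black bars for the median of the list. After genistein the medians are 1.56 for G2 and mitosis, 2.39 for ATF4 and -1.44 for cholesterol synthesis, and after BMP6 they are 1.25, 0.82 and 0.69.

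After BMP6, 43 genes were higher and 63 lower than in DMSO, 106 of 12661 in all. Of these 106 genes, 59 had either the BMP6 or the DMSO group listed at 0 in every library. A group at 0 throughout adds no spread of its own to the fit, and an exact 0 can be a failed estimate. Apart from HAMP, LCN15, a lipocalin gene, stood at 314 and 2286 FPKM and CRYAB, the gene of a small heat shock protein, at 54.9 and 126 FPKM in BMP6 1 and 2, and both were listed at 0 in all other libraries (limma adjusted p = 0.00315 each). CYP24A1, the vitamin D hydroxylase, rose from 0.597 ± 1.03 (SD, n = 3) to 88.8 ± 12.1 FPKM (SD, n = 2; log2 change 5.99 ± 0.57, limma adjusted p = 0.00751). CLIC3, the sodium channel subunit SCNN1A, the inhibin gene INHBE, S100P and AKR1C1 were the other large rises, with log2 changes from 4.34 to 6.23. SPINK1, a trypsin inhibitor, was listed at 0 in both BMP6 libraries and at 94.9 to 140 FPKM in DMSO (limma adjusted p = 0.000489). TNNT2, SMPX, SLC3A1, LINC01931, HVCN1, CYP7A1, PAQR6 and MUC15 were also listed at 0 after BMP6, from DMSO levels between 13.4 and 60 FPKM, and NPIPA1 fell by 6.16 on the log2 scale.

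BMP and SMAD target genes rose after BMP6 in 3 of 17 tested (9 higher and 1 lower adjusted over the list alone). These were HAMP, ATOH8, a transcription factor of the hepcidin promoter listed at 0 outside BMP6 and at 23.8 and 130 FPKM with it, and ID3, from 82.6 ± 28.4 to 703 ± 436 FPKM (log2 change 2.99 ± 0.51, limma adjusted p = 0.0467). Other targets did not pass: HEY1 (log2 change 2.46 ± 0.44, limma adjusted p = 0.0531), ID2 (2.08 ± 0.38, 0.0566), SMAD7 (1.74 ± 0.50, 0.137), GATA2 (1.54 ± 0.47, 0.152), DLX2 (1.91 ± 0.63, 0.175) and ID4 (1.42 ± 0.52, 0.203), and the homeobox gene MSX1 had -2.48 ± 0.83 (0.177). The list was called higher (camera adjusted p = 3.11e-07; adjusted p = 0.575 with an estimated correlation), with 15 of 17 members positive. The count of rises was 1 without DMSO 2, DMSO 3, genistein 3 or BMP6 1. Of 25 iron handling genes, 0 passed the limma threshold over all genes and 0 adjusted over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.495). TMPRSS6 had a log2 change of 0.32 ± 0.39.

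Among 22 glycolysis genes, 20 had a positive change after BMP6. SLC2A3, a glucose transporter, rose from 68.9 ± 17.5 to 459 ± 50 FPKM (SD, n = 3 and n = 2; log2 change 2.74 ± 0.34, limma adjusted p = 0.0198), and 3 genes passed when adjusted over the list alone. Lactate dehydrogenase LDHA (log2 change 2.08 ± 0.42, limma adjusted p = 0.0676) and the transporter SLC2A1 (553 ± 155 to 1759 ± 141 FPKM, 0.0787) did not pass over all genes. The list was called higher (camera adjusted p = 2.82e-06; adjusted p = 0.575 with an estimated correlation). Of 33 G2 and mitosis genes, limma called none over all genes, 22 were higher at an unadjusted p under 0.05 and 19 adjusted over the list alone, among them PRC1, HMMR, CCNB1 and TTK with log2 changes from 1.58 to 2.23. The mitosis list was called higher (camera adjusted p = 1.95e-12; adjusted p = 0.575 with an estimated correlation).

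SLC7A11 rose among 23 ATF4 genes after BMP6 (log2 change 2.51 ± 0.35; 7 adjusted over the list alone), and the list was called higher (camera adjusted p = 0.000254; adjusted p = 0.642 with an estimated correlation). AKR1C1, AKR1C2 and SLC7A11 rose among 20 NRF2 genes, while UGT1A6, whose exons are shared with other UGT1A genes, was listed at 0 (5 higher and 2 lower adjusted over the list alone). The NRF2 list was called higher (camera adjusted p = 0.0293; adjusted p = 0.875 with an estimated correlation). The fibrinogen genes FGA and FGG fell, FGA from 11356 ± 2314 to 664 ± 76.2 FPKM. They were the 2 of 25 STAT3 and acute phase genes that fell (2 higher and 4 lower adjusted over the list alone), and that list was not called (camera adjusted p = 0.694). TGFBI, which encodes a matrix protein, was among 2 of 17 TGF-beta targets that rose (4 adjusted over the list alone), and that list was not called (camera adjusted p = 0.153). The counts of NRF2 and TGF-beta list members that rose and of STAT3 and acute phase list members that fell (3, 2 and 2) were all 0 without DMSO 2, genistein 3 or BMP6 1. They were 0, 1 and 0 without DMSO 3, 1, 0 and 1 without genistein 1, 3, 1 and 1 without DMSO 1 or genistein 2, and 5, 2 and 5 without BMP6 2.

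Further lists called after BMP6 rested on few or no single genes past the limma threshold. Cholesterol synthesis had 0 of 24 past it (6 higher and 1 lower at an unadjusted p under 0.05, 4 higher adjusted over the list alone). It was called higher (camera adjusted p = 0.00189; adjusted p = 0.642 with an estimated correlation). Hypoxia response genes had 0 of 18 past the limma threshold (7 higher unadjusted, 4 adjusted over the list alone), with the smallest p for the mTOR inhibitor DDIT4 (log2 change 1.72), and were called higher (camera adjusted p = 0.00505; adjusted p = 0.642 with an estimated correlation). DNA replication genes had 0 of 31 (11 higher and 2 lower unadjusted, 1 and 1 adjusted over the list alone), with the smallest p for the helicase subunit MCM3 (log2 change 1.69), and were called higher (camera adjusted p = 0.0055; adjusted p = 0.875 with an estimated correlation). Fatty acid synthesis genes had 0 of 16 (4 higher and 1 lower unadjusted, 2 and 1 adjusted over the list alone), with the smallest p for the lipid droplet protein PLIN2 (log2 change 2.21), and were called higher (camera adjusted p = 0.0173; adjusted p = 0.642 with an estimated correlation). Replication-dependent histone genes had 0 of 13 (7 lower both unadjusted and adjusted over the list alone), with the smallest p for H2BC21 (log2 change -1.83), and were called lower (camera adjusted p = 0.000485; adjusted p = 0.642 with an estimated correlation). Here too the values cover only histone transcripts with a polyA tail. NF-kappa B genes were called lower with CXCL8 listed at 0 (2 of 11 adjusted over the list alone; camera adjusted p = 0.00333; adjusted p = 0.642 with an estimated correlation). Without BMP6 2 the NRF2, DNA replication, NF-kappa B and fatty acid synthesis calls were lost (camera adjusted p = 0.244, 0.194, 0.055 and 0.055), and without BMP6 1 the hypoxia and fatty acid synthesis calls (0.0518 and 0.06). The NRF2 call was also lost with quantile normalization (0.0861) and 2 groups only (0.0553), and the hypoxia call with genes above 0 in all libraries (0.0718) and with DMSO 1, genistein 2 and BMP6 1 left out (0.0503). Of 30 lists, camera called 9 higher and 2 lower after BMP6, fry called 2, and camera with an estimated correlation called 0.

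All 106 genes had BMP6 libraries that did not overlap the DMSO libraries, as did 33.3% of all genes tested, against 20% by chance. The count was 5 without DMSO 2, 15 without DMSO 3, 42 without genistein 1, 12 without genistein 3, 15 without BMP6 1 and 1999 without BMP6 2. The split of 43 higher and 63 lower was 30 and 89 without DMSO 1 and 437 and 1562 without BMP6 2. Of the 20 largest changes, HAMP, LCN15, CRYAB, SPINK1 and SMPX passed the threshold in each fit without 1 library. The other 15 lost it without DMSO 2, and 11 of them without genistein 3, 10 without DMSO 3 or BMP6 1, 7 without genistein 1, 5 without DMSO 1 and 3 without genistein 2. Their adjusted p was at most 0.222, with no change of direction. Of all 30 genes that the naming rule covers and that passed after BMP6, 5 passed in each such fit and 25 lost the threshold in 1 or more.

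The direct comparison asked where the treatments differed from each other: 81 genes were higher and 95 lower after genistein than after BMP6, 176 in all. Of these 176 genes, 58 had either the genistein or the BMP6 group listed at 0 in every library. Besides HAMP, the genes LCN15, CRYAB, ATOH8 and ANGPTL1, an angiopoietin-like secreted protein, were the most reduced, and all 4 were listed at 0 in the genistein libraries. CSTA, OSCAR and SPINK1, together with PALLD, an actin-associated protein, at 54.9 to 85.5 FPKM after genistein, were listed at 0 in both BMP6 libraries, and DUSP5 was at 121 ± 47.2 FPKM after genistein and 1.06 ± 1.5 after BMP6 (log2 difference 6.04 ± 0.62, limma adjusted p = 0.00541). SLC2A3 moved in opposite directions against DMSO and was lower after genistein by a log2 difference of -5.12 ± 0.34 (limma adjusted p = 0.00086). TMPRSS6 also differed, with 3.42 ± 0.649 FPKM after genistein and 27.6 ± 6.2 after BMP6 (log2 difference -2.69 ± 0.39, limma adjusted p = 0.0205).

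Cholesterol synthesis genes were lower after genistein than after BMP6 in 8 of 24 tested (21 adjusted over the list alone), and all 24 had a negative difference. They included LSS, ACAT2 and MSMO1, with log2 differences of -3.05, -3.25 and -3.07, and the list was called lower (camera adjusted p = 5.06e-22; adjusted p = 0.0725 with an estimated correlation). Fatty acid synthesis genes were lower in 4 of 16, namely SCD, PNPLA3, FADS2 and PLIN2 (1 higher and 10 lower adjusted over the list alone; camera adjusted p = 7.82e-08; adjusted p = 0.229 with an estimated correlation). SLC2A3 and PFKFB4, an enzyme that sets glycolytic flux, were lower among 22 glycolysis genes (7 adjusted over the list alone; camera adjusted p = 3.37e-07; adjusted p = 0.254 with an estimated correlation). HAMP, ATOH8 and ID2 were lower among 17 BMP targets (7 adjusted over the list alone; camera adjusted p = 4.52e-05; adjusted p = 0.316 with an estimated correlation). MCM3 was lower among 31 DNA replication genes (5 adjusted over the list alone; camera adjusted p = 7.82e-08; adjusted p = 0.317 with an estimated correlation), and CFI, a complement inhibitor, among 23 coagulation and complement genes (2 adjusted over the list alone; camera adjusted p = 0.000183; adjusted p = 0.345 with an estimated correlation).

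Higher after genistein than after BMP6 were DDIT3, ASNS, PPP1R15A and ATF3 among 23 ATF4 genes (8 adjusted over the list alone; camera adjusted p = 3.37e-07; adjusted p = 0.317 with an estimated correlation). DUSP5 and the early transcription factor EGR1 were higher among 23 immediate early genes (7 adjusted over the list alone; camera adjusted p = 7.82e-08; adjusted p = 0.229 with an estimated correlation). GCLC, GCLM, the modifier subunit of glutathione synthesis, and UGT1A6 were higher among 20 NRF2 genes (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00151; adjusted p = 0.386 with an estimated correlation). Camera also called the metallothionein list higher, with 0 of 11 past the limma threshold (4 higher both unadjusted and adjusted over the list alone; camera adjusted p = 0.0102; adjusted p = 0.229 with an estimated correlation), a call lost without BMP6 2 (0.266) and with genes above 0 in all libraries (0.634). The G2 and mitosis list did not differ detectably (0 of 33 past the limma threshold and 0 adjusted over the list alone, 1 higher and 1 lower unadjusted; camera adjusted p = 0.484).

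Of the other lists called lower after genistein than after BMP6, none had a gene past the limma threshold. Hypoxia response genes had 0 of 18 (1 higher and 8 lower unadjusted, 1 and 7 adjusted over the list alone; camera adjusted p = 0.000895; adjusted p = 0.317 with an estimated correlation), with LOX, a collagen crosslinker, at a log2 difference of -4.11. Heat shock genes had 0 of 14 (3 lower unadjusted, 0 adjusted over the list alone; camera adjusted p = 0.000408; adjusted p = 0.254 with an estimated correlation). PPAR-alpha genes had 0 of 16 (1 higher and 5 lower unadjusted, 3 lower adjusted over the list alone; camera adjusted p = 0.0035; adjusted p = 0.254 with an estimated correlation), a call lost without BMP6 1 (0.344) and with DMSO 1, genistein 2 and BMP6 1 left out (0.317). Hepatocyte markers had 0 of 28 (1 higher and 3 lower unadjusted, 0 adjusted over the list alone; camera adjusted p = 0.0332; adjusted p = 0.345 with an estimated correlation). The hepatocyte marker call was lost without genistein 1, genistein 3 or BMP6 1 (0.0726, 0.116 and 0.193) and with DMSO 1, genistein 2 and BMP6 1 left out (0.186). Of 30 lists, camera called 4 higher and 10 lower after genistein, fry called 8, and camera with an estimated correlation called 0.

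The 176 genes had libraries that did not overlap between the treatments, as did 28.9% of all genes tested, against 20% by chance, and the 10 largest differences passed the threshold in each fit without 1 library. Of all 33 that the naming rule covers and that passed, 16 did so and 17 lost the threshold in 1 or more fits, at adjusted p of at most 0.155. The count was 56 without DMSO 2, 83 without DMSO 3, 42, 96 and 48 without genistein 1, 2 and 3, and 629 without BMP6 2. The split of 81 higher and 95 lower turned to 484 and 145 without BMP6 2, and was 156 and 261 with median-of-ratios scaling. The 8 cholesterol synthesis genes were 3 without DMSO 2, 5 without DMSO 3, and 3, 3 and 4 without genistein 1, 2 and 3. The 4 ATF4 genes were 1 without DMSO 2, DMSO 3, genistein 2, genistein 3 or BMP6 1 and 0 without genistein 1. The 4 fatty acid synthesis genes were 0 without DMSO 2 or genistein 3 and 1 without DMSO 3, genistein 1, genistein 2 or BMP6 1. The 2 glycolysis genes were 4 without DMSO 1 and 1 without DMSO 2, BMP6 1 or any genistein library. The 2 immediate early genes were 1 without any genistein library and 8 without BMP6 2, and the 3 NRF2 genes were 5 without BMP6 2.

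Genes changed by both treatments against DMSO numbered 18 higher, 54 lower and 1 in opposite directions, SLC2A3. The shared rises included HAMP, CYP24A1, S100P, SLC7A11, AKR1C1, AKR1C2 and INHBE, and the shared falls CYP7A1, FABP1, FGA, CXCL8, TNNT2 and MUC15. Of the 54 shared falls, 32 were listed at 0 in all 5 treated libraries. Independent lists of these sizes would share 2.63 higher and 3.75 lower. The covariance of the log2 changes was 0.9423 against a simulated 0.1998, a difference of 0.7425, and the correlation across genes, which are not independent replicates, was 0.631 against 0.448. The simulated noise was independent between genes and so lacked trends that run through a whole library, such as that with GC. The difference therefore cannot be read as a shared response to the treatments alone. Part of the excess over independent lists may come from the 3 shared DMSO libraries, which are too few to split. The shared rises numbered 1 without DMSO 2, 5 without DMSO 3, 3 without genistein 1, 2 without genistein 3, 4 without BMP6 1 and 230 without BMP6 2, and the shared falls 1, 3, 26, 3, 4 and 623 without the same libraries.

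Markers of other cell types were mostly below the level tested. Of 10 fibroblast and stellate cell markers 1 was tested, of 8 endothelial markers 2, of 10 blood and immune markers 6 and of 8 biliary and other epithelial markers 4. After genistein, LYZ fell and CD68 rose among the immune markers, with log2 changes of -1.58 and 1.18, and CDH1 and SOX9 fell among the epithelial markers, with -1.97 and -2.30. Adjusted over the list alone, 1 endothelial marker was higher, 2 immune markers were higher and 1 lower, and 3 epithelial markers were lower. The 2 epithelial falls were 0 without DMSO 2 and 1 without DMSO 1, DMSO 3 or any genistein library. HepG2 is a carcinoma line that can itself express epithelial genes, so these falls need not reflect other cell types. After BMP6 none passed the limma threshold, and adjusted over the list alone 1 fibroblast marker was higher, PDGFRB (log2 change 2.05), and 2 epithelial markers were lower.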

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

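HAMP kept its direction and its limma threshold in 22 of 22 alternatives in each comparison. Its log2 changes ranged from 4.42 to 8.02 for genistein against DMSO (limma adjusted p from 3.77e-05 to 0.0191), from 11.32 to 15.31 for BMP6 against DMSO (8.19e-06 to 0.0306) and from -8.10 to -6.57 for genistein against BMP6 (0.000359 to 0.0295). It has no value among genes above 0 in all libraries, since it is listed at 0 in DMSO. Counts of changed genes follow in the order genistein against DMSO, BMP6 against DMSO and genistein against BMP6 (1527, 106 and 176 above). They were 2395, 338 and 424 with quantile normalization, 2616, 13 and 81 with 2 groups only, 5383, 8 and 38 with arrayWeights, 2653, 625 and 602 with the GC trend removed, and 2780, 503 and 883 with DMSO 1, genistein 2 and BMP6 1 left out. Median-of-ratios scaling gave 382 for BMP6 against DMSO and 417 for genistein against BMP6, a mean of at least 5 FPKM gave 38 for BMP6 against DMSO, and eBayes without the trend gave 173. Leaving out 1 library gave 229 to 2671, 5 to 1999 and 42 to 629, and with 1 BMP6 library left the lone sample is assumed to vary like the other groups. With the replicate number as a block the counts were 414, 4 and 7, the shared genes 2 higher and 0 lower, and their covariance 0.994. The block also ended 3 list calls: interferon after genistein (camera adjusted p = 0.0551), NRF2 after BMP6 (0.0529) and hepatocyte markers between the treatments (0.132). Replicate numbers showed no clear pairing: correlations of same-numbered deviations ranged from -0.247 to 0.286, and not every sample correlated best with its own number. Deviations within such small groups are tied to each other, so these values cannot exclude pairing. Shared higher genes (18 above) numbered 84 with median-of-ratios scaling, 74 with quantile normalization, 1 with 2 groups only, 1 with arrayWeights, 31 among genes above 0 in all libraries, 175 with the GC trend removed, 89 with the 3 libraries left out, and 1 to 230 without 1 library. Shared lower genes (54 above) numbered 89 with no filter, 11 with a mean of at least 5 FPKM, 180 with median-of-ratios scaling, 156 with quantile normalization, 3 with 2 groups only, 98 without the trend, 4 with arrayWeights, 240 with the GC trend removed, 161 with the 3 libraries left out, and 1 to 623 without 1 library. The covariance of the log2 changes (0.942 above) was 1.92 and 1.17 with pseudocounts of 0.1 and 0.5, 0.900 with no filter, 0.917 with a mean of at least 5 FPKM, 0.958 with median-of-ratios scaling and 0.915 with quantile normalization. It was 0.992 with arrayWeights, 0.736 among genes above 0 in all libraries, 0.906 with the GC trend removed, 0.623 with the 3 libraries left out, and 0.813 to 1.23 without 1 library. Of the gene lists, camera with an estimated correlation called 0, 0 and 0, fry called 2 after BMP6 and 8 between the treatments, and without 1 library the counts after BMP6 ranged from 7 to 12. Among values of named genes 5001 kept their direction and call, 306 gained a call, 688 lost one and 6 reversed, while list calls were kept in 812 cases and lost in 88. The reversed values were GATA2 in genistein against DMSO (-0.02492 with the 3 libraries left out) and, in genistein against BMP6, DLX2 (0.17 without genistein 3 and 0.17 without BMP6 2) and MSX1 (0.12 with the block, 0.31 without genistein 3 and 1.34 without BMP6 2), none of which passed the threshold. DLX2 and MSX1 kept their negative direction without BMP6 1 (-0.71 and -1.66) and with the 3 libraries left out (-1.11 and -1.84). For all of these the cause was not tested. The use of genes above 0 in all libraries, genes without a FAIL status, GC removal and the omission of 3 libraries were chosen after seeing the data. Depth is unknown, so it cannot be said how many of the values at 0 reflect few reads.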

Other observations

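Some members of lists that camera did not call rose after genistein. CDKN2B, a cell cycle inhibitor, rose from 1.17 ± 1.08 to 31.1 ± 10.4 FPKM (SD, n = 3 each; log2 change 3.99 ± 0.55, limma adjusted p = 0.00692), and the repressor BHLHE40 also rose, among 17 TGF-beta target genes (3 higher; 4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0797). The count was 5 without BMP6 1 or BMP6 2. AREG, an EGF receptor ligand, rose from 5.18 ± 3.41 to 141 ± 28.1 FPKM among 14 oestrogen responsive genes, of which RBBP8 also rose and PDZK1 fell (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.485). The death receptor TNFRSF10B, GDF15 and PLK3 rose among 25 p53 targets (6 adjusted over the list alone; camera adjusted p = 0.201), and that count was 0 without DMSO 2, 1 without genistein 3 and 7 without BMP6 1 or BMP6 2. CYP1A1, the classical gene of the aryl hydrocarbon receptor, rose by 4.16 ± 0.72 as the only one of 7 such genes (1 adjusted over the list alone; camera adjusted p = 0.453). The chaperone genes DNAJB9 and HYOU1 rose among 19 genes of the unfolded protein response (2 adjusted over the list alone; camera adjusted p = 0.3), and DDIT4 and the angiogenic factor VEGFA among 18 hypoxia genes (2 adjusted over the list alone; camera adjusted p = 0.657). The counts of 2 for the oestrogen, unfolded protein and hypoxia lists were each 1 without any DMSO or genistein library. Of 25 STAT3 and acute phase genes, SOCS3 and IL6R rose and FGA fell (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.759). SOCS3 was listed at 0 in DMSO and stood at 3.83 to 4.13 FPKM after genistein, and IL6R rose from 8.41 ± 2.18 to 38.5 ± 5.94 FPKM. The STAT3 and acute phase rises numbered 0 without DMSO 2, genistein 1 or genistein 3.

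Hepatocyte marker, heat shock and DNA replication lists held members that fell after genistein, and none of these lists was called. TTR, which encodes transthyretin, fell from 7848 ± 594 to 1307 ± 421 FPKM (SD, n = 3 each; log2 change -2.64 ± 0.52, limma adjusted p = 0.0193). FOXA1, a hepatic transcription factor, and APOC3, an apolipoprotein, also fell among 28 hepatocyte markers, and TAT, a tyrosine catabolic enzyme, rose (4 lower and 1 higher; 5 and 1 adjusted over the list alone; camera adjusted p = 0.0604). The heat shock genes HSPA1A and HSPA1B, near-identical copies whose reads cannot be told apart with certainty, fell among 14 (4 adjusted over the list alone; camera adjusted p = 0.236). CCNE2, UNG and E2F2, genes of the G1 to S transition and base repair, fell among 31 DNA replication genes (3 adjusted over the list alone; camera adjusted p = 0.0816), with CCNE2 listed at 0 in all 5 treated libraries. Falls in the hepatocyte, heat shock and replication lists numbered 2, 0 and 2 without DMSO 1, 0, 0 and 0 without DMSO 2, and 1, 0 and 1 without DMSO 3. They numbered 1, 0 and 0 without genistein 1, 0, 0 and 1 without genistein 2, 0, 0 and 0 without genistein 3, and 8, 4 and 7 without BMP6 1 or BMP6 2. Of 48 ribosomal protein genes limma called 0 over all genes and 0 adjusted over the list alone, with 4 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0548). Of 22 glycolysis genes PFKP rose and SLC2A3 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.643). Of 14 Notch and WNT target genes HEY1 rose and RNF43 and TNFRSF19 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.245). Those 2 falls were 0 without DMSO 2, DMSO 3, genistein 2 or genistein 3.

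The patterns weighed below were chosen after the main results were seen, and the GC trend was tested because the gene names of the second component pointed to it. Each prediction was written before its test was run.

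The BMP6 libraries differed more from each other (correlation 0.847) than other replicates did. BMP6 2 correlated more with DMSO 2, DMSO 3 and each genistein library (0.850 to 0.912) than with BMP6 1. BMP6 1 correlated more with genistein 3 (0.889) than with BMP6 2. The BMP6 pair therefore did not group together. Across genes, the difference between BMP6 1 and BMP6 2 had a Spearman correlation of -0.543 with transcript GC content and 0.416 with transcript length. The trend was not confined to BMP6: relative to the mean of all libraries, genistein 3 and BMP6 1 had Spearman correlations of -0.338 and -0.375 with GC. With length they had 0.265 and 0.275. BMP6 2 and DMSO 3 went the other way, with 0.421 and 0.254 for GC and -0.361 and -0.203 for length. Deviations of genistein 3 and BMP6 1 from their group means correlated at 0.594. With 2 BMP6 libraries the value for BMP6 2 is then fixed at -0.594, so it cannot tell which BMP6 library departs. With the GC trend of each library removed, the correlation of the BMP6 pair went from 0.846 to 0.886 over 11993 genes. A technical GC or length bias could account for part of the difference, but these values do not separate it from a difference between the cultures. No biological explanation was tested.

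More genes changed after genistein (1527) than after BMP6 (106). With 2 genistein libraries the lowest count was 280, without genistein 3, which was still more than 1.5 times the 106 after BMP6, or the 12 after BMP6 in the same fit. The smaller number of BMP6 libraries therefore does not account for the whole difference. Its size depends on the BMP6 library kept: with 1 BMP6 library the BMP6 count was 15 without BMP6 1 and 1999 without BMP6 2, where genistein gave 2660 and 2671. The larger spread of the BMP6 pair remains as an explanation that was not tested. In 10 splits of the 6 DMSO and genistein libraries the real one gave 1527 genes and the highest other gave 1, and 10 splits cannot give a share under 0.05.

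Camera called the G2 and mitosis list higher after both treatments, with median log2 changes of 1.56 after genistein and 1.25 after BMP6, and with an estimated correlation it called neither (adjusted p = 0.415 with an estimated correlation after genistein, adjusted p = 0.575 with an estimated correlation after BMP6). Of its 33 members 19 passed the limma threshold after genistein and 0 after BMP6 (24 and 19 adjusted over the list alone). These transcripts have a low GC content (median 43.2% against 48.7% for all genes tested). With the GC trend removed the medians were 1.39 and 1.28, and without DMSO 1, the lowest library (mean log2 of 5.71 against 6.24 in DMSO 2 and DMSO 3), they were 1.37 and 1.12. Neither the GC trend nor DMSO 1 alone accounts for the pattern. The mean log2 of the list was 7.48, 7.45 and 7.46 in genistein 1, 2 and 3 and 7.12 and 7.37 in BMP6 1 and 2. Both comparisons use the same 3 DMSO libraries, so the calls after genistein and after BMP6 are not independent. No biological explanation was tested.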
